A study of Homo sapiens with 8 samples.

How the data were processed

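Poly(A)-selected RNA of 4 diffuse large B cell lymphoma lines was measured in 8 paired-end stranded libraries, 2 per line. DOHH2 and SUDHL4 are labelled germinal-center B cell like (GCB), and HBL1 and TMD8 activated B cell like (ABC). Per the labels' protocols, RNA was extracted with Trizol and the cells grew in RPMI medium with 5% serum. The deposited values are FPKM, that is fragments per kilobase of gene and scaled to the mapped fragments of a library, made by the authors and rounded to 2 decimals, per the file headers and the values. Per the submitters' processing notes, bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.6.1c, RSEM 1.3.2 and the build hg38 were used; the notes give no roles, settings or annotation release. The columns sum to different totals, from 851413 to 1232610. Counts and read totals are not in the values used here, so the depth was estimated from the smallest step between low FPKM values of genes of 400 to 1000 nt at 0.6 FPKM or less. It came to 74.6 to 149 M fragments per library, with 89.4 to 93.5% of the values used within 0.2 of a whole multiple. The estimate is approximate and no counting interval was drawn from it.

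The table has 58381 genes with versioned Ensembl IDs and symbols. In 29 symbols turned into dates by a spreadsheet the name was restored from the ID. The version of 56933 IDs is that of GENCODE release 29, and coordinates, on GRCh38, are given for these alone. Tests used log2(FPKM + 1) of the 14790 genes at 1 FPKM or more in at least 2 libraries. Values were used as deposited, with no further normalization, and median-ratio size factors computed from the FPKM were the main alternative; they ranged from 0.639 to 1.27.

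The subtype comparison used the means of the 4 lines, 2 against 2, since subtype is a property of a line, with 2 residual degrees of freedom. HBL1 against TMD8, SUDHL4 against DOHH2 and the F test over the 4 lines used all 8 libraries with 1 mean per line and 4 residual degrees of freedom. All were fitted with limma 3.58.1 in R 4.3.3, with moderated variances and an intensity trend, and p-values were adjusted by Benjamini-Hochberg. A gene passed, and is said to have risen or fallen, at an adjusted p under 0.05 with a log2 difference of at least 1 in size, or for the F test a range of line means of at least 1. Differences are coded as ABC minus GCB, HBL1 minus TMD8 and SUDHL4 minus DOHH2.

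A total of 18 gene lists with 381 entries was tested with camera, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 18 lists, and with fry, adjusted in the same way, for the direction of each list without comparison with other genes. The lists are MHC-I and MHC-II antigen presentation, T and NK cell ligands, the cell-of-origin classifier genes higher in GCB and higher in ABC, the germinal center programme, plasma cell differentiation, B cell receptor signalling, immunoglobulin constant regions, NF-kB targets, interferon-stimulated genes, PRC2 and chromatin regulators, glycosphingolipid synthesis, ER-associated degradation, folate and thymidylate metabolism, apoptosis regulators, proliferation, and markers of T, NK, myeloid, red, stromal and epithelial cells. All entries matched a gene, 2 of them through another symbol. The lists, the tests, the thresholds, the alternative settings listed below (apart from those said to be added) and the rule for named genes were fixed before the data were examined. The rule takes, per comparison and among genes that passed, the 10 largest differences in each direction and up to 2 rises and 2 falls per list. Among the genes it adds whatever their result are HLA-B, HLA-C, B2M, NLRC5, HLA-DRA, CD74, CIITA, CD58, EZH2, SPPL3, B3GNT5, TYMS, SYVN1, SEL1L, MME, BCL6, IRF4 and PRDM1, and it allows the 2 MHC and the 2 classifier lists in full. Immunoglobulin and T cell receptor segments other than constant regions are not named, and not every gene the rule takes is described.

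The code was tested on simulated data with 200 genes changed among 14790. The subtype test on line means called 0, 0 and 21.5% of genes changed by 1, 2 and 4 on the log2 scale and no unchanged gene, whereas treating libraries as replicates called 1735 to 1755 unchanged genes. HBL1 against TMD8 called 35.5, 95.5 and 98.5% of them and SUDHL4 against DOHH2 40, 95 and 100%, with 1 to 4 unchanged genes. The simulated genes varied independently, with no shift or length trend common to the libraries of a line or subtype. These counts of unchanged genes therefore do not give the rate of false calls in the data.

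The alternatives changed 1 choice at a time: the offset, the filter, the scaling (size factors, quantiles, a common total), the variance model, the thresholds, the treatment of libraries as replicates, a replicate block, and leaving out each library or line. Added after the data were seen were the removal of mitochondrial genes, the removal of a trend on gene length with and without size factors, 1 library per line, and subtraction of a SUDHL4 share from HBL1. Further calculations and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and statmod 1.5.0 served the correlation between libraries of a line.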

Results

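Poly(A) RNA was sequenced from 4 established diffuse large B cell lymphoma lines with 2 libraries each. DOHH2 and SUDHL4 are labelled germinal-center B cell like (GCB), and HBL1 and TMD8 are labelled activated B cell like (ABC), the 2 main subtypes of this lymphoma. The series title concerns genetic screens for modulators of the recognition of lymphoma cells through MHC-I and MHC-II. The labels name no treatment. Expression was given as FPKM for 58381 genes, of which 23504 were listed at 0 in all 8 libraries. Read totals are not in the values used here. The spacing of low values gives an estimated depth of 74.6 and 85.5 M fragments for the DOHH2 libraries, 132 and 106 M for HBL1, 110 and 118 M for SUDHL4, and 110 and 149 M for TMD8. Below, a level is the mean FPKM ± SD of the 2 libraries of a line, and a log2 difference is given ± SE on the scale of log2(FPKM + 1), which understates differences at low levels.

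The libraries of a line lay close together, with correlations across genes of 0.988 to 0.996 between libraries of a line, 0.852 to 0.919 between lines of a subtype and 0.777 to 0.804 between subtypes. The ABC libraries held more mitochondrial transcripts, at 27.9 and 36.5% of all FPKM in HBL1 and 33.3 and 27.1% in TMD8, against 11.4 and 11.8% in DOHH2 and 13.4% in both SUDHL4 libraries. Ribosomal protein genes took 25.2 to 26.4% in HBL1, 32.4 to 38.0% in TMD8 and 27.4 to 29.9% in the GCB libraries. The median difference between libraries of a line was 0.05 on the log2 scale in DOHH2, 0.06 in SUDHL4, 0.21 in HBL1 and 0.15 in TMD8. Of 14790 genes tested, the median gene was lower in the ABC than in the GCB lines, at -0.43 on the log2 scale, and higher in HBL1 than in TMD8, at 0.38. List medians between the subtypes are therefore given relative to -0.43, and a call that ends when this shift is removed with size factors is named.

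**Figure D1:**
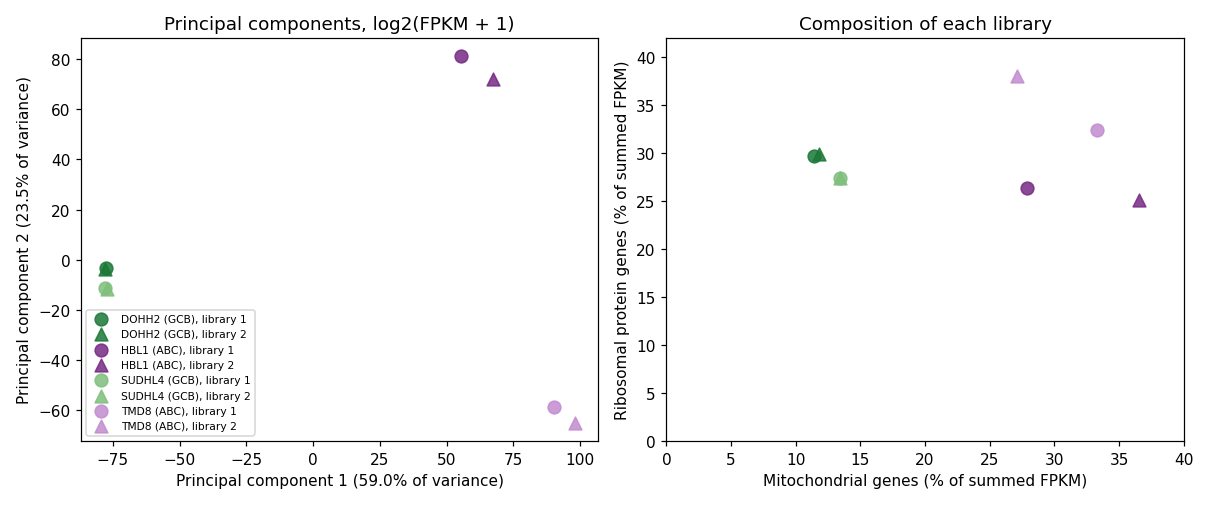
Left, the 8 libraries on the first principal components of log2(FPKM + 1), where component 1 holds 59.0% of the variance and separates the subtypes, and component 2 holds 23.5%. Right, the share of FPKM from mitochondrial genes against the share from ribosomal protein genes in percent, where the ABC libraries sit between 27.1 and 36.5% mitochondrial and the GCB libraries between 11.4 and 13.4%.

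The ABC lines differed from the GCB lines in genes long used to tell the subtypes apart. MME (ENSG00000196549.10, chromosome 3 from 155024124 to 155183729 on GRCh38), the germinal center surface peptidase CD10, was at 131 ± 3.75 in DOHH2 and 178 ± 9.21 in SUDHL4, against 1.41 ± 0.297 in HBL1 and 0.06 ± 0.0283 in TMD8 (log2 difference -6.59 ± 0.56, limma adjusted p = 0.0123). IRF4 (ENSG00000137265.14, chromosome 6 from 391739 to 411447), a transcription factor of activated B cells and plasma cells, was at 28.2 ± 3.89 in HBL1 and 48.5 ± 7.88 in TMD8 and at 0.01 and 0.015 in the GCB lines (5.22 ± 0.54, adjusted p = 0.0215). IGHM (ENSG00000211899.9, chromosome 14), the heavy chain of IgM, was listed at 0 in all 4 GCB libraries, at 3435 ± 478 in HBL1 and at 708 ± 83.1 in TMD8 (adjusted p = 0.00703). In total 400 genes passed the threshold, 109 higher and 291 lower in the ABC lines. After division by size factors 124 passed, 74 higher and 50 lower, and 122 genes were shared by the 2 counts, 72 higher and 50 lower.

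The 2 classifier lists, drawn from published classifiers made on other samples, moved in the directions of their names. Of 19 tested genes of the list higher in ABC, 7 rose and none fell, 13 rose when adjusted over the list alone, and the median stood 3.10 above that of all genes (camera adjusted p = 9.07e-15). With an estimated correlation the list did not pass (adjusted p = 0.164), and by fry it did (adjusted p = 0.0454). Beside IGHM and IRF4, the risers were BATF (7.22 ± 0.51), TNFRSF13B, the BAFF and APRIL receptor TACI (6.65 ± 0.75), the cyclin CCND2 (5.48 ± 0.86), CYB5R2 (4.96 ± 0.57) and ENTPD1 (3.88 ± 0.50), with adjusted p between 0.00704 and 0.0367. Against the list went IL16, at -1.15 ± 0.55 and at -0.54 with size factors. BLNK went against it as deposited, at -0.53 ± 0.52 and at 0.13 with size factors; neither passed. Of 13 genes higher in GCB, 8 fell and none rose, 10 fell when adjusted over the list alone, and the median was -2.87 relative to all genes (adjusted p = 3.58e-06, and adjusted p = 0.164 with an estimated correlation and 0.0158 by fry). STAP1 (-5.59 ± 0.64), ASB13 (-5.32 ± 0.49) and the receptor S1PR2 (-4.51 ± 0.49) fell with and without size factors, as MME did. BCL6 (-3.59 ± 0.61), the repressor that maintains the germinal center state, fell as deposited but not with size factors (adjusted p = 0.0745), and so did MYBL1, ITPKB and LRMP. NEK6 alone on this list had a positive difference, at 1.3 ± 1.27 (adjusted p = 0.542), low in DOHH2 only. The transcription factor LMO2, on the GCB list, went against the grouping, at 65.7 ± 8.49 in TMD8, 16.9 ± 0.325 in DOHH2, 7.26 ± 0.0283 in SUDHL4 and 0.48 ± 0.184 in HBL1.

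**Figure D2:**
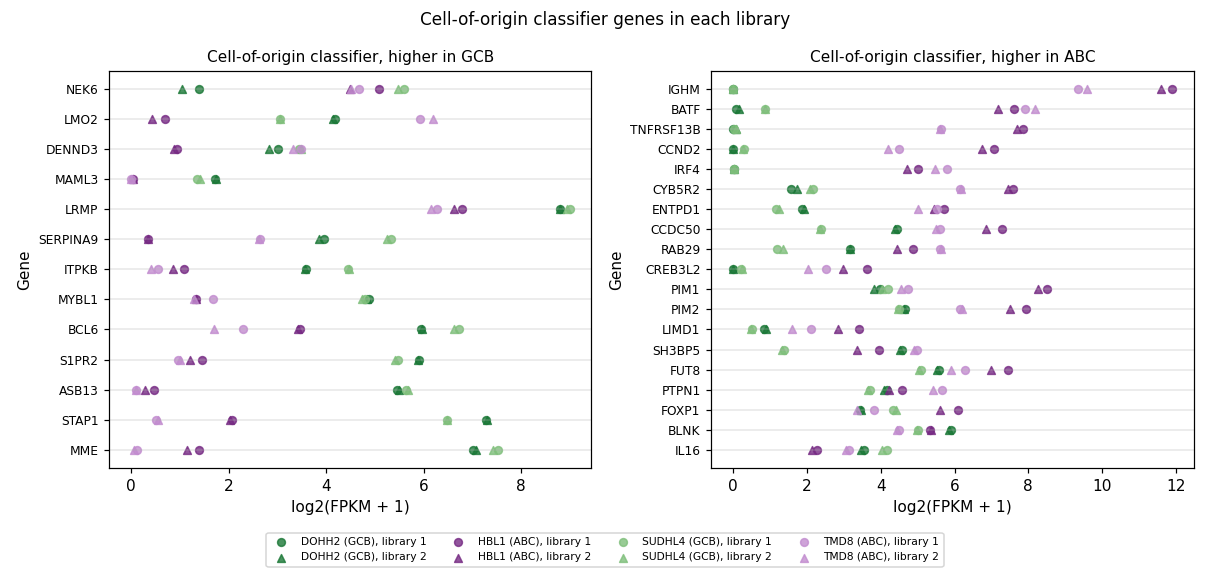
Expression of the classifier genes in each of the 8 libraries as log2(FPKM + 1), with the list higher in GCB in one panel and the list higher in ABC in the other. MME, at 131 and 178 FPKM in the GCB lines, and IRF4, at 28.2 and 48.5 FPKM in the ABC lines, separate the subtypes, while LMO2 was highest in TMD8.

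Other genes among the largest subtype differences included the interferon-inducible IFI27 (chromosome 14 from 94104836 to 94116698), at 412 ± 60.9 in HBL1 and 341 ± 39.7 in TMD8 against 0.25 and 0.115 in the GCB lines (8.31 ± 0.42). The hyaluronan receptor CD44 was at 229 ± 35.5 and 241 ± 7.31 in the ABC lines, listed at 0 in DOHH2 and at 1.03 ± 0.148 in SUDHL4. MGST1, YBX3, BEX3 and the cancer-testis genes CT45A1 and CT45A3 were listed at 0 in all GCB libraries and lay between 77.9 and 341 FPKM in the ABC lines; the CT45A copies are nearly identical, so their split is uncertain. Lower in the ABC lines were PRDX2, a peroxiredoxin (-5.89 ± 0.48), TUBB3 (-6.09 ± 0.49), RGCC (-6.11 ± 0.58), AC140481.1 (-6.00 ± 0.72) and MAPK10 (-5.62 ± 0.57). BMP7, listed at 0 in TMD8 and at 0.23 ± 0.0849 in HBL1 against 205 ± 1.54 in DOHH2 and 30.9 ± 0.46 in SUDHL4, passed as deposited and not with size factors (adjusted p = 0.0647). Some of the low HBL1 values are close to a fixed small share of the SUDHL4 level: MME was listed in HBL1 at 0.794% of its level in SUDHL4, PRDX2 at 0.707%, BMP7 at 0.744% and HMCES at 1.09%, in the range of genes detected in SUDHL4 and hardly in DOHH2 or TMD8, whose median was 0.872%. RGCC at 1.42% and TUBB3 at 1.44% stood higher, and so did VPREB3 at 1.53%, CD27 at 3.24%, STAP1 at 3.57% and S1PR2 at 3.60%.

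Some germinal center genes fell in the ABC lines. Of 19 genes of the germinal center programme 16 had negative and 3 positive differences, 8 fell and none rose, 14 fell when adjusted over the list alone, and the median was -2.31 relative to all genes (adjusted p = 4.85e-06, and adjusted p = 0.164 with an estimated correlation and 0.0046 by fry). Those that fell included HMCES (-6.13 ± 0.57), GCSAM (-5.97 ± 0.73) and VPREB3 (-5.62 ± 0.40). With size factors 4 fell. Plasma cell genes went both ways, 2 rising and 2 falling of 16 (adjusted p = 0.177). SLAMF7 (4.86 ± 0.67) and the elongation factor ELL2 (4.20 ± 0.73) rose, whereas CD27 (-4.71 ± 0.60) and CD38 (-4.03 ± 0.67) fell, CD38 not with size factors. As deposited and not relative to all genes, the list's median difference was positive, at 0.67, and its mean negative, at -0.14. Relative to all genes its median was 1.09. PRDM1, the regulator of plasma cell fate, was at 2.0 ± 0.141 in HBL1 and 13.0 ± 3.48 in TMD8 and at 0.035 and 0.01 in the GCB lines, short of the threshold (2.65 ± 0.79, adjusted p = 0.113). Of 14 immunoglobulin constant genes IGHM alone passed, and 2 rose when adjusted over the list alone (median 1.99 relative to all genes, adjusted p = 1.43e-04, and adjusted p = 0.164 with an estimated correlation and 0.0158 by fry).

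Some targets of NF-kB and some genes induced by interferon rose in the ABC lines. Of 27 NF-kB targets 22 had positive differences, 7 rose and none fell, and 12 rose and 2 fell when adjusted over the list alone, with a median of 2.01 relative to all genes (adjusted p = 7.55e-11, and adjusted p = 0.174 with an estimated correlation and 0.0745 by fry). CD44 (7.37 ± 0.51 on the log2 scale) and the cytokine subunit EBI3 (5.11 ± 0.78) were among them. With size factors 5 rose. Of 31 interferon-stimulated genes 26 had positive differences, 3 rose and 1 fell, and 12 rose and 1 fell when adjusted over the list alone (median 2.10, adjusted p = 1.07e-10, and adjusted p = 0.312 with an estimated correlation and 0.0928 by fry). IFI27 and the antiviral GTPase MX1 (4.06 ± 0.68) rose, and SAMHD1 (-2.55 ± 0.46) fell as deposited but not with size factors. The mitochondrial share of the same libraries was 27.1 to 36.5% in the ABC and 11.4 to 13.4% in the GCB lines.

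A few genes of cell division and of nucleotide supply fell in the ABC lines as deposited. Of 24 proliferation genes 22 had negative differences, 3 fell and none rose, 17 fell when adjusted over the list alone, and the median was -1.26 relative to all genes (adjusted p = 4.11e-06, and adjusted p = 0.387 with an estimated correlation and 0.0838 by fry). The helicase subunits MCM7 (-3.42 ± 0.57) and MCM6 (-3.20 ± 0.48) were among them. Of 21 genes of folate and thymidylate metabolism 18 had negative differences, 5 fell, 9 when adjusted over the list alone, with a median of -0.91 relative to all genes (adjusted p = 2.21e-04, and adjusted p = 0.387 with an estimated correlation and 0.0745 by fry). RRM2B (-3.26 ± 0.49) and the serine hydroxymethyltransferase SHMT2 (-3.00 ± 0.38) fell, and TYMS, thymidylate synthase, was at 247 ± 4.32 in DOHH2, 231 ± 0.615 in SUDHL4, 45.4 ± 11 in HBL1 and 75.5 ± 2.86 in TMD8 (adjusted p = 0.0567). With size factors no gene of these 2 lists passed. Of 21 PRC2 and chromatin regulators RBBP7 alone fell (-2.48 ± 0.45, not with size factors), 7 fell when adjusted over the list alone, and the median was -0.85 relative to all genes (adjusted p = 0.00191, and adjusted p = 0.626 with an estimated correlation and 0.126 by fry). EZH2, the PRC2 methyltransferase, had a difference of -1.41 ± 0.40 (adjusted p = 0.103). The mitochondrial share was higher in the ABC libraries, 27.1 to 36.5% against 11.4 to 13.4%.

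Apart from the MHC and ligand lists described below, the remaining lists gave no call by camera or fry between the subtypes. None of 21 B cell receptor genes, 12 glycosphingolipid genes or 19 apoptosis regulators passed, and UBE2J1 alone fell among 21 genes of ER-associated degradation (-3.46 ± 0.62, not with size factors). When adjusted over the list alone, 2 rose and 7 fell of the B cell receptor genes, 1 rose and 2 fell of the glycosphingolipid genes, 1 apoptosis regulator rose and 2 genes of ER-associated degradation fell. The plasma cell list had 3 rises and 3 falls. The camera adjusted p was 0.475 for B cell receptor genes, 0.545 for glycosphingolipid genes, 0.119 for apoptosis regulators and 0.504 for ER-associated degradation. As deposited and not relative to all genes, the median of the glycosphingolipid list was -0.084 and its mean -0.12. Relative to all genes its median was 0.34, and the set test, which compares with other genes, pointed upward as well. SPPL3, an intramembrane protease, had a difference of -0.02 ± 0.45, SEL1L of -0.39 ± 0.57 and SYVN1, both parts of an ER ubiquitin ligase, of -0.89 ± 0.39; with size factors the sign of SPPL3 and SEL1L turned, to 0.62 and 0.22. B3GNT5 stayed under the filter, between 0.15 and 0.72 FPKM. Of 29 markers of T, NK, myeloid, red, stromal and epithelial cells 6 reached the filter and none passed (adjusted p = 0.862).

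Some MHC-II genes fell in the ABC lines, and no MHC-I gene passed in either direction. Of 19 MHC-II genes 18 had negative differences, 6 fell and none rose, 12 fell when adjusted over the list alone, and the median was -2.12 relative to all genes (adjusted p = 7.69e-06, and adjusted p = 0.387 with an estimated correlation and 0.0838 by fry). HLA-DOB (ENSG00000241106.6, chromosome 6), part of the peptide exchange machinery, was at 27.9 ± 0.0636 in DOHH2, 44.2 ± 1.20 in SUDHL4, 0.465 ± 0.0636 in HBL1 and 0.47 ± 0.0849 in TMD8 (-4.62 ± 0.52, adjusted p = 0.0259). HLA-DRB5 (-4.29 ± 0.65), HLA-DPA1 (-3.72 ± 0.51), HLA-DRB1 (-3.58 ± 0.51), HLA-DOA (-3.37 ± 0.59) and HLA-DMB (-3.14 ± 0.51) fell as deposited, and with size factors HLA-DOB alone passed. HLA-DOB was listed in HBL1 at 1.05% of its SUDHL4 level, HLA-DPB1 at 1.19% and HLA-DQA1 at 1.14%, near the median of 0.872% of genes detected in SUDHL4 and hardly in DOHH2 or TMD8; HLA-DRB5 at 1.81% and HLA-DPA1 at 3.70% stood higher. HLA-DRA (ENSG00000204287.13, chromosome 6 from 32439842 to 32445046) was at 273 ± 5.13 in DOHH2, 517 ± 7.72 in SUDHL4, 34.2 ± 0.919 in HBL1 and 117 ± 6.62 in TMD8 (-2.55 ± 0.64, adjusted p = 0.0841). The invariant chain CD74 (-1.61 ± 0.72) and CIITA, the MHC-II transactivator (-1.71 ± 0.55), did not pass either, at adjusted p = 0.234 and 0.127.

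None of 21 tested MHC-I genes passed, over all genes or over the list alone, while the list as a whole stood 0.95 above the median of all genes (camera adjusted p = 3.00e-04, and adjusted p = 0.164 with an estimated correlation and 0.0745 by fry), with 16 differences positive and 5 negative. HLA-B had a difference of 2.06 ± 0.76, HLA-C of 1.25 ± 0.77, B2M of 0.98 ± 0.33 and NLRC5, the MHC-I transactivator, of 2.33 ± 0.70, with adjusted p from 0.112 to 0.362. PDIA3, with the lowest adjusted p of the list, went the other way (-1.49 ± 0.36, adjusted p = 0.0765), as did TAP2 (-1.0 ± 0.43) and PSMB8 (-0.73 ± 0.40). HLA genes are polymorphic and share sequence, so the split of reads among them is uncertain, for the MHC-II genes and the other comparisons as well. Among 19 T and NK cell ligands CD70 rose (4.82 ± 0.63, adjusted p = 0.0284), from 4.57 ± 0.099 in DOHH2 and 0.82 ± 0.0566 in SUDHL4 to 102 ± 22.3 in HBL1 and 78.3 ± 13.3 in TMD8, and when adjusted over the list alone 4 rose and 2 fell (median 1.37 relative to all genes, adjusted p = 2.81e-04, and adjusted p = 0.164 with an estimated correlation and 0.00189 by fry). CD58, the ligand of CD2, went against the subtype grouping, at 16.3 ± 0.799 in TMD8, 3.37 ± 0.0636 in DOHH2, 0.245 ± 0.0495 in SUDHL4 and 0.005 ± 0.00707 in HBL1. The mitochondrial share, higher in the ABC libraries, moved with these groups.

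**Figure D3:**
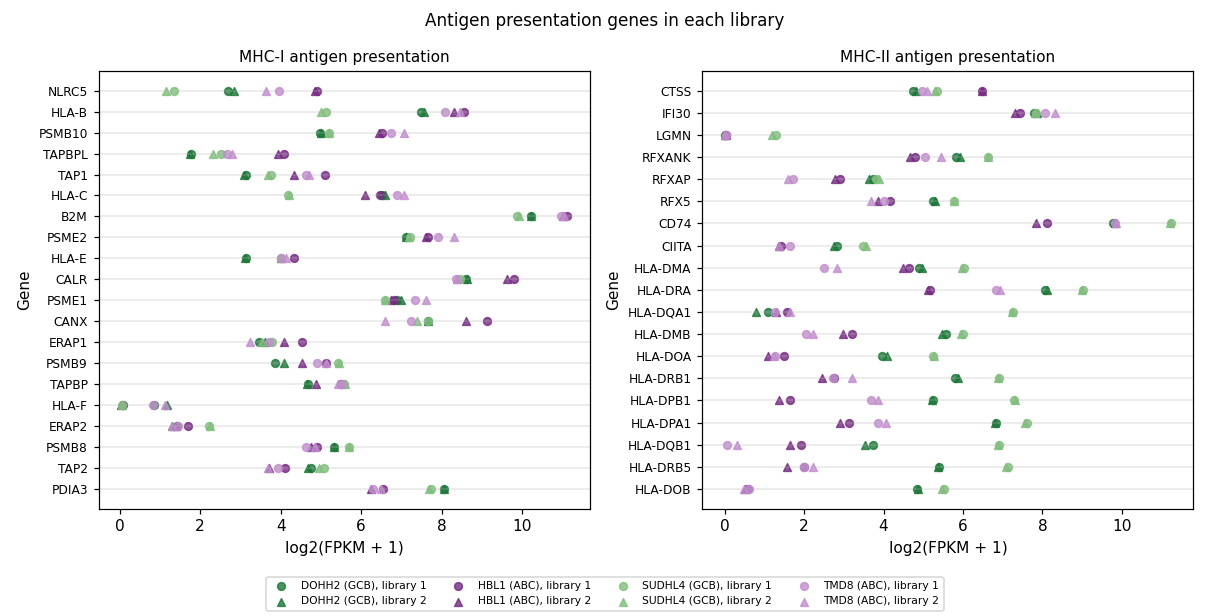
Expression of genes of the MHC-I and MHC-II lists in each of the 8 libraries as log2(FPKM + 1), 1 panel per list. In the MHC-II panel HLA-DRA spans from 34.2 FPKM in HBL1 to 517 in SUDHL4, and in the MHC-I panel HLA-B spans from 32.6 FPKM in SUDHL4 to 349 in HBL1.

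The subtype test used limma on the means of the 4 lines, 2 against 2, with Benjamini-Hochberg adjustment over 14790 genes. In the values as deposited, both ABC lines lay above both GCB lines in 2327 genes and below in 6244. Together these are 57.9%, where chance without a common shift gives 33.3%. The median gene was lower in the ABC lines, at -0.43, and such a shift by itself adds genes to the lower group. The excess over 33.3% is therefore not evidence of subtype differences of single genes. The count of 400 genes that passed fell to 0 when no filter on low values was used (limma, 4614 genes at an unadjusted p under 0.05). Without replicate 1 of HBL1 it rose to 663, and without replicate 2 of HBL1 the calls of SAMHD1, RBBP7, ITPKB and HLA-DOA ended.

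HBL1 and TMD8, labelled as 1 subtype, differed in many genes. TCL1A (ENSG00000100721.10, chromosome 14 from 95709967 to 95714196 on GRCh38), a coactivator of AKT, was at 549.6 ± 4.42 in TMD8 and 1.13 ± 0.41 in HBL1 (-8.03 ± 0.13, limma adjusted p = 1.37e-07), and its neighbor TCL1B was at 169 ± 14.2 in TMD8 and listed at 0 in HBL1. VIM, vimentin, was at 56.4 ± 0.502 in TMD8 and 0.02 ± 0 in HBL1, and the proteasome chaperone PSMD9 at 73.8 ± 7.84 and 0.575 ± 0.177. In the other direction SVIP (7.78 ± 0.26), the cancer-testis antigen CTAG2 (7.18 ± 0.18, listed at 0 in both GCB lines) and the interferon-inducible LY6E (7.04 ± 0.14) were higher in HBL1. In total 4769 genes passed, 3520 higher and 1249 lower in HBL1; after division by size factors 4333 passed, 2128 higher and 2205 lower.

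Further genes higher in HBL1 were PPDPF (6.85 ± 0.13), LILRA4 (6.41 ± 0.14), the iodide transporter SLC5A5 (6.33 ± 0.17), UCHL1 (5.91 ± 0.21), IL17RB (5.88 ± 0.10), MEST (5.68 ± 0.19) and RP11-291L15.2 (5.59 ± 0.08). Lower were SIGLEC6 (-6.23 ± 0.20), S100A10 (-6.21 ± 0.15) and CTD-2319I12.1 (-5.57 ± 0.15). The short genes RP11-328L11.1, a processed pseudogene, RF02216 and VTRNA1-2 were listed at 0 in HBL1 and at 151, 115 and 78.7 FPKM in TMD8. Their annotated lengths of 89 to 93 nt lie below the estimated fragment lengths of 140 to 195 nt, so their FPKM are uncertain. Of 16 plasma cell genes 11 rose and 2 fell as deposited (adjusted p = 0.135), and 9 rose and 2 fell with size factors (adjusted p = 0.0464). With an estimated correlation, as deposited, the list did not pass (adjusted p = 0.897). JCHAIN (3.79 ± 0.08) and XBP1 (3.46 ± 0.12) were higher in HBL1, and PRDM1 (-2.20 ± 0.16) and SDC1 (-1.49 ± 0.07) in TMD8. IRF4 had a difference of -0.76 ± 0.14 as deposited and passed with size factors, at -1.25. No other list passed by camera, as deposited or with size factors, and no list passed with an estimated correlation (adjusted p = 0.897 for all 18). By fry, which does not compare with other genes, the MHC-I, MHC-II, germinal center and immunoglobulin lists did not pass (adjusted p from 0.0908 to 0.289), and the others did, at 1.20e-04 to 0.0266. Of these the ligand and GCB classifier lists pointed down and the rest up. These fry tests used the values as deposited, where the median gene was 0.38 higher in HBL1. A list that only follows this shift points up. With size factors the median of the folate list went from 0.46 to 0.0051, and that of the plasma cell list from 1.57 to 1.09.

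MHC and ligand genes went both ways between HBL1 and TMD8. Of 21 MHC-I genes 4 rose and none fell as deposited (adjusted p = 0.306), whereas with size factors 1 rose and 4 fell. CANX (1.94 ± 0.24) was higher in HBL1 on both scales. CALR (1.35 ± 0.09), TAPBPL (1.29 ± 0.12) and NLRC5 (1.08 ± 0.14) passed as deposited and not with size factors. HLA-C went from -0.69 ± 0.13 as deposited to -1.18 with size factors, HLA-B from 0.18 ± 0.14 to -0.31 and B2M from 0.07 ± 0.08 to -0.43, so that HLA-B and B2M changed sign. Of 19 MHC-II genes 4 rose and 3 fell as deposited (adjusted p = 0.159), and 2 rose and 5 fell with size factors. HLA-DMA (1.91 ± 0.13), HLA-DQB1 (1.59 ± 0.15), RFXAP (1.19 ± 0.10) and CTSS (1.45 ± 0.09) rose, the last pair not with size factors, and HLA-DPB1 (-2.26 ± 0.12), CD74 (-1.86 ± 0.11) and HLA-DRA (-1.74 ± 0.08) fell. CIITA differed little, at -0.10 ± 0.12. Among 19 ligands 2 rose and 4 fell on both scales (adjusted p = 0.519), with CD58 (-4.10 ± 0.08) and LGALS9 (-4.47 ± 0.13) higher in TMD8 and TNFSF9 (2.22 ± 0.13) and ULBP2 (1.34 ± 0.06) in HBL1. HLA-DQB1, MME, TCL1A and PSMD9 were listed in HBL1 at 2.08, 0.794, 0.680 and 0.696% of their SUDHL4 level; MME passed between HBL1 and TMD8 at 1.18 ± 0.11, and the call ended once the SUDHL4 share was subtracted, at -0.084.

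Within the other lists, counts as deposited are followed by those with size factors. The ABC classifier genes went 11 up and 2 down in HBL1, and 7 up and 6 down with size factors, among them PIM1 (3.73 ± 0.13) and FOXP1 (2.27 ± 0.20) higher and SH3BP5 (-1.29 ± 0.18) and PTPN1 (-1.14 ± 0.14) lower. The GCB classifier went 3 up and 3 down on both scales, with BCL6 (1.45 ± 0.18) and STAP1 (1.52 ± 0.08) up and LMO2 (-5.49 ± 0.13) and DENND3 (-2.49 ± 0.11) down. The germinal center programme went 5 up and 6 down, then 4 and 6, BACH2 (2.09 ± 0.11) up and BCL7A (-3.07 ± 0.16) down among them. Of 14 immunoglobulin constant genes 5 rose and 5 fell on both scales, with IGLC2 at 397 ± 4.16 in HBL1 and 19.5 ± 1.03 in TMD8, and IGHG4 at 32.0 ± 4.50 and 241 ± 5.09; reads can be shared among these paralogs. Interferon-stimulated genes went 13 up and 3 down, then 11 and 4, with IFI44L (4.33 ± 0.11) up and IFITM1 (-3.06 ± 0.13) down, and NF-kB targets 11 up and 4 down, then 9 and 5, with CCL3 (2.76 ± 0.08) up and IL6 (-3.03 ± 0.14) down. B cell receptor genes went 6 up and none down as deposited but 3 up and 3 down with size factors, with PRKCB (2.91 ± 0.25) up. Chromatin regulators went 7 up, then 3, with RBBP4 (1.97 ± 0.09), and proliferation genes 7 up, then 5, with CCNA2 (2.29 ± 0.14). Apoptosis regulators went 9 up and 3 down, then 6 and 6, with BMF (2.48 ± 0.16) up and BCL2L11 (-3.20 ± 0.17) down. Glycosphingolipid genes went 7 up and 1 down, then 2 and 1, with UGCG (2.34 ± 0.21) up and ST3GAL5 (-3.48 ± 0.09) down. ER-associated degradation went 8 up and 1 down, then 2 and 2, with HERPUD1 (2.49 ± 0.16) up and UBE2J1 (-1.76 ± 0.10) down. Folate metabolism went 4 up and none down, then 1 and 2. Of the markers of other cell types 3 rose and 1 fell on both scales, TRAC (4.28 ± 0.17) most. The adjusted p of these 14 lists ranged from 0.158 to 0.672.

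This test and the next used limma over all 8 libraries with 4 residual degrees of freedom and Benjamini-Hochberg adjustment, and their p-values measure only the spread between libraries, since the labels do not say whether the libraries of a line come from separate cultures. The difference grew with gene length, from a median of 0 in the shortest of 5 equal classes of genes to 0.69 in the longest. The surplus of genes higher in HBL1 ended with size factors and with the length trend removed (1794 higher, 1872 lower). Both settings also take out the overall level of each library, leaving median differences of 0.045 and 3e-04. The end of the surplus therefore cannot tell a length trend from a shift of all genes. The call of NLRC5 ended without replicate 2 of TMD8 and that of PTPN1 without replicate 2 of HBL1.

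SUDHL4 had more MHC-II transcripts than DOHH2 and a different type of immunoglobulin light chain. Of 19 MHC-II genes 9 rose in SUDHL4 and none fell, and all 19 differences were positive (camera adjusted p = 5.75e-06, and adjusted p = 0.990 with an estimated correlation and 7.26e-04 by fry). HLA-DQA1 (ENSG00000196735.11, chromosome 6 from 32628179 to 32647062 on GRCh38) was at 150.4 ± 1.20 in SUDHL4 and 0.92 ± 0.283 in DOHH2 (6.31 ± 0.18, limma adjusted p = 5.84e-07), HLA-DQB1 at 118 ± 0.785 and 11.5 ± 1.24 (3.25 ± 0.15), HLA-DPB1 rose by 2.07 ± 0.12 and CD74 by 1.43 ± 0.11. The split of reads among the polymorphic HLA genes is uncertain here too. IGKC (ENSG00000211592.8, chromosome 2 from 88857161 to 88857683), the kappa constant region, was listed at 0 in DOHH2 and at 2331 ± 85.5 in SUDHL4, while the lambda constant region IGLC3 was at 4374 ± 2.04 in DOHH2 and 23.1 ± 1.12 in SUDHL4. In total 2342 genes passed, 1379 higher and 963 lower in SUDHL4, and the median gene differed by 0.03.

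A few MHC-I genes differed between these lines, in both directions, and 16 of 21 did not pass. The immunoproteasome subunit PSMB9 rose in SUDHL4 (1.47 ± 0.20, adjusted p = 8.37e-04), while HLA-B (-2.46 ± 0.14), HLA-C (-2.36 ± 0.13) and NLRC5 (-1.51 ± 0.14) fell. The list as a whole did not pass (2 up, 3 down, adjusted p = 0.977). HLA-DRA had a difference of 0.92 ± 0.08, below the threshold of 1 on the log2 scale. Among ligands CD48 (4.96 ± 0.13) and LGALS9 (2.97 ± 0.13) were among 4 that rose, and CD200 (-2.22 ± 0.06) and CD58 (-1.81 ± 0.08) among 5 that fell.

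Other large differences were in GTSF1, CDKN2A (chromosome 9 from 21967753 to 21995301), IGLL5 and RP11-328L11.1, all listed at 0 in DOHH2 and at 169.5, 125, 108 and 104 FPKM in SUDHL4, where IGLL5 overlaps IGLC1 and can share its reads, and in decorin, DCN (6.63 ± 0.09), the tetraspanin CD82 (6.22 ± 0.25) and NSG1 (5.80 ± 0.08). The FPKM of RP11-328L11.1, a gene of 93 nt, is uncertain. RP11-15B24.5 passed as well, with a large error (5.85 ± 1.91). PHGDH (chromosome 1 from 119648411 to 119744226), of serine synthesis, and LUZP6, which shares its locus with another gene, were listed at 0 in SUDHL4 and at 128 ± 6.96 and 75.1 ± 22.4 in DOHH2. LY6E, listed at 0 in SUDHL4, S100A10 (-7.01 ± 0.15), PRKAR2B (-6.46 ± 0.15), TRBC2 (-6.04 ± 0.10), UCHL1 (-5.89 ± 0.21), AC096579.15, which overlaps IGKC (-6.06 ± 0.08), and RP11-386I14.4 (-5.94 ± 0.30) were also higher in DOHH2. Among classifier genes, NEK6 (4.32 ± 0.21) and SERPINA9 (1.39 ± 0.09) rose and LMO2 (-1.12 ± 0.13) fell of 13 on the GCB list, and 3 of 19 on the ABC list fell, with SH3BP5 (-3.18 ± 0.18) among them. In the germinal center programme 2 rose and 3 fell, TCL1A (3.53 ± 0.13) and SUGCT (-3.69 ± 0.08) among them.

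The counts in the other lists were small: 3 up and 1 down of 16 plasma cell genes, with XBP1 (-2.52 ± 0.12) down, 4 up of 21 B cell receptor genes, with INPP5D (1.70 ± 0.15), 3 up and 3 down of 14 immunoglobulin constant genes, 5 up and 2 down of 27 NF-kB targets, with CD40 (1.81 ± 0.11) up and TNFAIP2 (-3.23 ± 0.09) down, and 6 up and 3 down of 31 interferon-stimulated genes, with IFITM2 (4.20 ± 0.19) and ISG15 (2.67 ± 0.22) up and IFITM1 (-4.00 ± 0.13) down. The annotation of IFITM2 spans IFITM1 on the same strand, so the split of reads between them is uncertain. CAD (1.0 ± 0.11) rose alone among 21 folate genes, 1 of 21 chromatin regulators and 3 of 12 glycosphingolipid genes rose, ST8SIA1 (1.83 ± 0.08) among the latter, 5 apoptosis regulators rose and 2 fell, with BIK (2.80 ± 0.10) up and HRK (-2.06 ± 0.08) down of 19, and no gene of proliferation or ER-associated degradation passed. Of the markers of other cell types DCN rose and TRAC (-2.86 ± 0.17) fell. EZH2 differed by -0.17 ± 0.08 (adjusted p = 0.127) and SEL1L by 0.22 ± 0.32. Apart from the MHC-II list none passed by camera, with adjusted p from 0.203 to 0.977. The NF-kB targets did with an offset of 0.1 (upward, adjusted p = 0.0422), but not with an estimated correlation (adjusted p = 0.990) or by fry (0.0911), both at the offset of 1. By fry the GCB classifier (adjusted p = 0.0412), immunoglobulin (0.0319), glycosphingolipid (0.0283) and other-cell lists (3.51e-04) passed as well, all upward. In that order their medians were 0.19, 0, 0.23 and 0.046 and their means 0.45, 0.43, 0.36 and 0.66. Camera pointed down for the immunoglobulin list. These passes by fry therefore do not show a rise of the typical gene of a list. In this comparison and in that of HBL1 with TMD8, the counts adjusted over the list alone equaled those over all genes for all 18 lists. Median and mean had opposite signs in the MHC-I, ligand and chromatin lists here, and in the ligand, GCB classifier and germinal center lists between HBL1 and TMD8; in the ER-associated degradation list here and the MHC-I and apoptosis lists of HBL1 against TMD8 both were positive and the set test pointed down. The call of RP11-15B24.5, listed at 0.02 and 128 in the HBL1 libraries, ended without any 1 library of DOHH2, SUDHL4 or TMD8, and that of CAD without replicate 2 of DOHH2 or of SUDHL4 and with size factors (0.99).

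Over all 4 lines, the limma F test with Benjamini-Hochberg adjustment found 11389 of 14790 genes with a range of line means of at least 1 on the log2 scale. Of the MHC-I list 14 of 21 genes differed among the lines and of the MHC-II list 18 of 19, with ranges up to 3.63 for NLRC5 and 6.70 for HLA-DQB1. HLA-B was at 184 ± 7.03 in DOHH2, 32.6 ± 1.97 in SUDHL4, 349 ± 42.6 in HBL1 and 309 ± 55.1 in TMD8. HLA-C was lowest in SUDHL4, at 17.3 ± 0.431 against 93.0 ± 3.43 in DOHH2, 77.4 ± 13.9 in HBL1 and 125 ± 10.6 in TMD8. B2M, the invariant light chain of MHC-I, ranged from 954 ± 19.9 in SUDHL4 and 1200.5 ± 0.431 in DOHH2 to 2065 ± 74.3 in TMD8 and 2166 ± 108 in HBL1. CD74 was lowest in HBL1, at 252 ± 35.2, with 891 ± 15.8 in DOHH2, 914 ± 7.86 in TMD8 and 2394 ± 37.6 in SUDHL4, and CIITA was at 10.5 ± 0.41 in SUDHL4, 5.90 ± 0.311 in DOHH2, 1.83 ± 0.375 in TMD8 and 1.63 ± 0.0849 in HBL1. The test shows differences between libraries of the lines and not between subtypes.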

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

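The removal of mitochondrial genes, of a length trend and of a SUDHL4 share, and the choice of 1 library per line, were chosen only after the data were seen. The subtype count, 400 genes by limma, moved with most settings. It was 0 with no filter on low values (4614 at an unadjusted p under 0.05), and 734 with a mean FPKM of at least 5, 973 after rescaling to a common total, 124 with size factors and 109 with quantile normalization. It was 237 with no variance trend, 642 with robust variances, 9 at an adjusted p under 0.01, 187 with the length trend removed and 170 with size factors and the length trend removed. With libraries as replicates it was 5718 and with the replicate block as well 5722, and in these fits the 2 libraries of a line count as separate samples. With the duplicate correlation of 0.932 it was 1643. That fit treats the libraries of a line as correlated but still counts each library in its degrees of freedom. With library 1 of each line it was 190 and with library 2 it was 429. Leaving out each line in turn gave 0 every time (limma, 1577 to 4676 at an unadjusted p under 0.05), but 2 lines against 1 leave 1 residual degree of freedom, so these zeros are not evidence that the calls depend on a line. Leaving out each library gave 305 to 663, the highest without HBL1 replicate 1. The share of genes higher in the ABC lines was 27.3% as deposited, 59.7% with size factors, 56.0% with quantiles and 58.3% with the length trend removed, but 14.6% after rescaling to a common total and 16.5% with a mean FPKM of at least 5, and 88.9% of the 9 genes at an adjusted p under 0.01. Removal of the length trend also takes out the overall level of each library, as size factors do. Its 187 genes and its share of 58.3% therefore do not single out length. The cause was not tested for the filters, scalings and variance models.

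Between HBL1 and TMD8 the count of 4769 became 2834 with a mean FPKM of at least 5, where fewer genes were tested, and 10659 with no fold threshold, and 4303 to 5288 without a library. The share higher in HBL1 was 73.8% as deposited, 49.1% with size factors, 81.2% after rescaling to a common total and 82.2% without mitochondrial genes. SUDHL4 against DOHH2, at 2342, became 3708 with an offset of 0.1, 1103 with a mean FPKM of at least 5 and 7598 with no fold threshold, and 2322 to 2342 without a library. The F test, at 11389, became 6815 with a mean FPKM of at least 5, and 11059 to 11565 without a library. The replicate numbers carried a shared difference in HBL1 and TMD8 but not in other pairs of lines. Residuals correlated at 0.24 between HBL1 and TMD8 and at -0.02 to 0.02 between other lines. In HBL1 and TMD8, library 2 minus library 1 fell from the shortest to the longest genes, by -0.25 and -0.24. Whether the numbers mark a batch was not tested. The replicate block, fitted over all lines, gave 4770, 2346 and 11399 genes. The other settings run for these counts stayed within 1.5 times the reported value. Among named genes and lists, 30 lost and 12 gained a call with size factors, and 32 and 8 with the length trend removed. With an estimated correlation all 13 list calls made by camera as deposited ended, counted per comparison. Of named genes with a call, MME between HBL1 and TMD8 alone changed sign, at -0.084 after subtraction of the SUDHL4 share, which removes what MME had in HBL1. Some named genes without a call changed sign with size factors, such as HLA-B (-0.31) and B2M (-0.43) between HBL1 and TMD8 and SPPL3 (0.62), SEL1L (0.22) and BLNK (0.13) between the subtypes. Without read totals the precision of low values is not known, and the offset of 1 compresses differences of genes near 1 FPKM.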

Other observations

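All tests in this part were chosen only after the result was seen, except those of length within HBL1, of the lower SUDHL4 genes and of silent neighbors; the genes named here outside the rule were chosen after their values were seen. Some cancer-testis genes were on in the ABC lines and not in the GCB lines. Of 9 CT45A genes, 6 were at 1 FPKM or more in HBL1 and 7 in TMD8, with the highest at 151 and 341 FPKM, and none in the GCB lines. Of 12 MAGEA genes 2 reached 1 FPKM in HBL1 and 1 in TMD8, of 10 MAGEB genes 1 in each ABC line, and none in the GCB lines. CTAG transcripts reached 164 FPKM in HBL1 and 0.13 in TMD8, and were listed at 0 in both GCB lines. The SSX family did not follow this grouping, with 1 of 9 genes at 1 FPKM or more in every line, at 15.9 FPKM in HBL1 and 14.7 in DOHH2. Of 13 GAGE, 5 XAGE and 3 MAGEC genes none reached 1 FPKM in any line, and of 6 PAGE genes 1 did, in TMD8 at 1.46 FPKM. Reads of these near-identical copies can be shared, so the number of genes on is uncertain.

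Medians per autosome were taken of log2 values after size factors, each gene relative to its median over the 4 lines and each line relative to its median over genes. Chromosome 7, with 447 genes, was at -0.30 in HBL1 and -0.17 in TMD8, against 0.16 in both GCB lines. Chromosomes 4 and 8 were also negative in both ABC lines and positive in both GCB lines, and chromosomes 9 and 14 the reverse. Chromosome 18 was at -0.22 in DOHH2 and between 0.09 and 0.12 in the other lines, and chromosome 19 at 0.37 in TMD8 and between -0.12 and 0.06 in the others. Size factors leave a trend on gene length between the subtypes, at -0.81 from the shortest to the longest genes. Gene length may therefore enter these medians, which was not tested.

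Chance cannot be weighed by splits of the lines, since the 4 lines make 3 splits into pairs, too few for a share under 0.05. The real split gave 400 genes, the highest other 0, and 1 split reached the real count.

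Most genes had lower values in the ABC than in the GCB lines, with a median of -0.43. The larger mitochondrial share is not enough alone, since the median was still -0.41 with mitochondrial genes left out and the rest rescaled. With all genes kept and rescaled to a common total the median was -0.67, so on that scale leaving them out reduced the shift. The shift followed gene length, from 0.21 in the shortest of 5 equal classes of genes to -0.74 in the longest, a difference of -0.95, and the same trend was seen between the libraries of HBL1, at -0.25, and of TMD8, at -0.24, against 0 in DOHH2 and -0.02 in SUDHL4, while HBL1 minus TMD8 rose with length by 0.69. Since libraries of 1 line share a subtype, a length bias of library preparation or RNA integrity may explain part of the shift; the count of genes does not decide it, at 187 with the trend removed, 124 with size factors and 170 with both. A difference of the subtypes in long genes remains open as well and was not tested.

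Genes of SUDHL4 appeared in HBL1 at a small share of their level. The 12 genes, immunoglobulin segments included, at 20 FPKM or more in SUDHL4 and under 0.5% of that in DOHH2 and TMD8 had a median HBL1 share of 0.872%, among them EYA2 at 0.791%, DAPL1 at 0.842%, DCN at 0.858% and THY1 at 0.884%, and of the protein-coding genes at 20 FPKM or more in SUDHL4, 0 were listed in HBL1 under 0.25%, whereas 5 to 59 were in the other 11 ordered pairs of lines. DOHH2 material is excluded by its own genes, with a median share of 0.0122%, and reads misassigned in every library by the 9 of 27 SUDHL4 genes low in DOHH2 that were under 0.1% in TMD8, although 4 of the 27, all short pseudogenes or small RNAs, were under 0.1% in HBL1 too. These values are consistent with SUDHL4 cells, RNA or library entering both HBL1 libraries, which the data cannot separate, although CDKN2A at 3.77% and MTAP at 25.6% stand above the share. The median of the lower genes, at 5 to 20 FPKM, was 1.64%, with 1.82% in HBL1 library 1 and 0.786% in library 2, where the small RNAs RF00019, RNU6-112P and RF01956 were listed at 0, against 1.08 and 0.723% for the higher genes, and leaves the size of the share open.

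Genes silent in TMD8 and expressed in the other lines tended to lie side by side. Neighbors were counted among 8500 autosomal protein-coding genes at 5 FPKM or more in at least 1 line. There were 22 neighboring silent pairs, 21 in TMD8, 1 in HBL1 and 0 in DOHH2 and SUDHL4. In 1000 shuffled gene orders the mean was 0.613 and the maximum 4, and 0 orders reached 22, which argues against chance placement of single genes. All silent neighbors in TMD8 were zinc finger genes, and the shuffle also scatters gene families that lie in clusters. It cannot tell silence of neighbors from silence of members of a clustered family. Of 61 genes silent in TMD8 30 were zinc finger genes, of the 210 among 7626 protein-coding genes expressed in the other lines, with 1 silent in DOHH2 and none in HBL1 or SUDHL4, and silent genes in runs formed 2 groups on chromosome 19 of GRCh38, 14 from 19865886 to 24129961 and 10 from 52527652 to 53392217, with 1 more pair, ZNF736 and ZNF680, on chromosome 7 from 64307459 to 64563106. Inside the groups on chromosome 19, 4 genes, ZNF430, ZNF714, ZNF431 and ZNF611, were at 1 FPKM or more in TMD8, which argues against the loss of 1 whole segment per group. Several smaller losses or silencing of the groups may explain the pattern and were not tested apart.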
